A study of Arabidopsis thaliana with 12 samples.

How the data were processed

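Polyadenylated RNA from leaves of 5-week-old plants of 4 genotypes was sequenced in 12 libraries, 3 per genotype, per the labels. Per the submitters' processing notes, reads were handled with TopHat2, HTSeq and limma on TAIR10, with no versions and no strand given. The deposited table holds read counts per gene and library with replicates kept apart and a lowest gene sum of 101, so genes with fewer reads were not analysed here. It also holds log2 CPM per library by the authors, and for 3 comparisons the authors' log2 changes with an adjusted p-value (FDR) each. The authors' comparison columns were used as an alternative only. The deposited log2 values follow from the counts with a constant offset per library. Of the gene codes 18777 were found in the reference table, and codes were matched by locus without any conversion of coordinates. Coordinates are printed for *EDS1A* alone, from TAIR10.1.

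Library totals were 21403388, 21867688 and 27854906 counts for Col-0, 25228804, 32018583 and 23281173 for TPR1-GFP, 19628974, 23355823 and 28345801 for TPR1-GFP sid2-1, and 21516906, 23362262 and 21195080 for TPR1-GFP eds1-2. The 10 most abundant genes took 12.2 to 13.6% of counts in Col-0, 7.64 to 8.47% in TPR1-GFP, 9.64 to 10.2% in the sid2-1 line and 11.4 to 12.3% in the eds1-2 line. TMM factors ran from 0.888 to 0.934, 1.08 to 1.10, 1.01 to 1.05 and 0.961 to 0.990 in that order. Replicates of a genotype had chi-square values of 6.70 to 38.4 per degree of freedom and log2 correlations of 0.974 to 0.990, so none is a copy of another. Counts cannot tell native *TPR1* from the transgene, and near-identical copies (*EDS1A* and *EDS1B*, the *PDF1.2* group with *PDF1.3*, several antenna genes, *KIN2* and its neighbour, *CYP71A12* and its neighbour) can exchange reads.

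Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 18877, libraries were scaled by TMM, and the quasi-likelihood model with robust estimation was fitted to all 12 libraries with genotype as the only term. P-values were adjusted by Benjamini and Hochberg over all genes tested, and genes under 0.05 were called. Fold changes are those of this fit, and CPM values are group means with the SD over 3 libraries. Each standard error (SE) was derived as the size of the log2 change divided by the square root of the F statistic of its test. It is thus no direct estimate of sampling error, least of all for genes with few counts. Changes given as a fold are a ratio of group levels that was computed here from the deposited counts. A gene without counts in a group is given as "at least" a fold, from a floor of 3 counts over its 3 libraries. For 1 to 3 counts the ratio has a 95% interval, and floor and interval cover counting error only. Replicate numbers paired libraries across genotypes in part only. Of 18 pairs 8 correlated above 0.1, among them all 3 of the sid2-1 line with Col-0 (0.172, 0.22 and 0.309) but none of TPR1-GFP with Col-0. The eds1-2 line with TPR1-GFP had 0.356, 0.355 and −0.0527, and 7 of 12 libraries were closest to their own number. A pairing is thus not excluded. The main fit used no block, and the replicate number as a block was run as an alternative.

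Comparisons were TPR1-GFP against Col-0, each double line against TPR1-GFP, the double lines against each other, and each double line against Col-0. Genes called in TPR1-GFP against Col-0 were counted by whether they were called alike in each double line against Col-0, with the share of their log2 change that was kept. Overlaps are set beside the number that independent lists would give and beside 20 simulated draws of unchanged groups. In each draw all 12 libraries, the shared control included, were simulated anew from the means of the shared group. The other splits of 3 and 3 libraries were run for every comparison. Genes with locus codes AT3G40000 to AT3G55000 around *EDS1* were compared with the rest by Fisher's exact test, for calls in each double line and for genes that differ in the eds1-2 line from the 3 other genotypes in 1 direction. Only the calls against TPR1-GFP were part of the planned test.

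The 24 gene lists were fixed before the data were examined: SA synthesis and its activators, SA response, N-hydroxypipecolic acid pathway, EDS1 family and helper immune receptors, sensor receptors, pattern-triggered immunity, cysteine-rich kinases, camalexin and indole glucosinolates, the *DND* channels, the TOPLESS family, the MYC and ERF branches of jasmonate responses, photosynthesis, auxin and cell expansion, cell cycle, endoplasmic reticulum folding and secretion, senescence, abscisic acid and cold, heat shock, clock, and markers of floral organs, root, vascular cells and epidermis. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted over the lists of a comparison. Per list, genes called over all genes tested are given, with the count adjusted over the list alone where that differs. Camera takes genes as nearly independent, and camera with an estimated correlation and fry were run as alternatives. Where the report gives the direction of a list, it holds under each scaling tried except as stated in the closing section.

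Genes were named by a rule set beforehand: the genes that define the lines in every comparison, the 6 largest rises and 6 largest falls in 4 comparisons among called genes whose libraries do not overlap with a mean of at least 1 CPM, up to 4 members per list and comparison with the smallest adjusted p, and 13 immune genes. The text gives a selection of these.

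The method was tested on simulated data in which 100 genes were changed 2-fold and 100 changed 4-fold. Each comparison had a single draw with genes independent of each other. Changed genes were taken above a floor of expression, with as many rises as falls. Far fewer genes changed than were called in the real data, so scaling under broad change and noise shared between genes were not tested. The edgeR test recovered 71 and 96 of them for TPR1-GFP against Col-0, 68 and 94 for the eds1-2 line against TPR1-GFP, and 70 and 91 for the sid2-1 line against TPR1-GFP, with 6, 16 and 11 false among 173, 178 and 172 calls. For the comparisons of the sid2-1 line with the eds1-2 line, the eds1-2 line with Col-0 and the sid2-1 line with Col-0, it recovered 68 and 94, 65 and 97, and 73 and 92, with 6, 8 and 18 false among 168, 170 and 183 calls. The last is a false share of 9.84%, and with 8.99% for the eds1-2 line against TPR1-GFP and 6.4% for the sid2-1 line against TPR1-GFP, 3 of the 6 comparisons lay above the nominal 5%.

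Alternatives were DESeq2 1.42.0, its size factors, upper-quartile scaling, no filter, a filter of 5 CPM in 3 libraries, the replicate number as a block, only the 6 libraries of a comparison, each library left out in turn, a threshold of 0.01, limma-voom, leaving out the genes around *EDS1*, and the authors' columns. No scaling beyond the library total was added after the data were seen, as were 11 further gene families. Pseudocount alternatives apply to normalised tables and were not run. Genotypes were taken from the labels, and no read sequence was used here.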

Results

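Leaf transcripts were sequenced from 5-week-old *Arabidopsis thaliana* plants of 4 genotypes, with 3 libraries per genotype and 12 in all. Col-0 is the wild-type accession. The TPR1-GFP line carries a GFP-tagged copy of TPR1, a corepressor of transcription of the TOPLESS family, and 2 further lines hold that transgene in plants with the sid2-1 or the eds1-2 mutation. The sid2-1 allele affects ICS1, the isochorismate synthase behind most pathogen-induced salicylic acid (SA), and eds1-2 affects EDS1, a lipase-like protein through which TIR-type immune receptors signal. Plants had no treatment and grew on soil with 10 h of light at 22 °C and 60% humidity. Library totals ran from 19628974 to 32018583 counts, and 18877 genes were tested. The labels name independent experiments but tie no replicate number to an experiment, so the p-values measure only the spread between these 12 libraries.

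The genes that define the lines came first. *TPR1* stood at 74.1, 73.5 and 68.3 counts per 1e6 counts (CPM) in the Col-0 libraries and at 1539, 1748 and 1617 CPM in the TPR1-GFP libraries, a count that pools the native gene and the transgene. It stood at 776, 1305 and 1222 CPM in the sid2-1 line and at 1048, 1327 and 990 CPM in the eds1-2 line. *EDS1A*, at chromosome 3 positions 17755329 to 17758147 of TAIR10.1, had 60.81, 31.95 and 29.62 CPM in Col-0, 130, 148 and 173 CPM in TPR1-GFP, and 13.48, 15.99 and 15.68 CPM in the eds1-2 line. Its neighbour *EDS1B* is a near-identical copy, so reads can be assigned to either. *ICS1* had 49.9, 26.6 and 10.3 CPM in Col-0 and 208, 266 and 368 CPM in TPR1-GFP, against 132, 136 and 157 CPM in the sid2-1 line and 30.03, 25.88 and 23.26 CPM in the eds1-2 line. The sid2-1 allele is a base change in the coding sequence, so the *ICS1* level does not test the genotype of those plants. Component 1 of a principal component analysis held 59.7% of the variance and set TPR1-GFP and the sid2-1 line apart from Col-0 and the eds1-2 line, and component 2 held 15.9%.

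**Figure D1:**
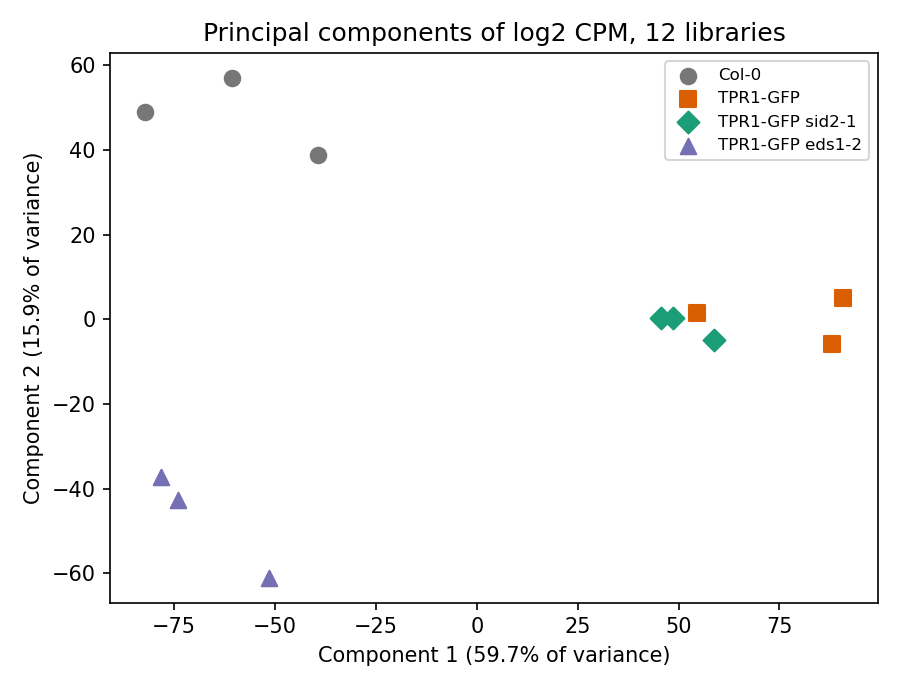
Principal components of log2 CPM for the 12 libraries, 3 per genotype.

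**Figure D2:**
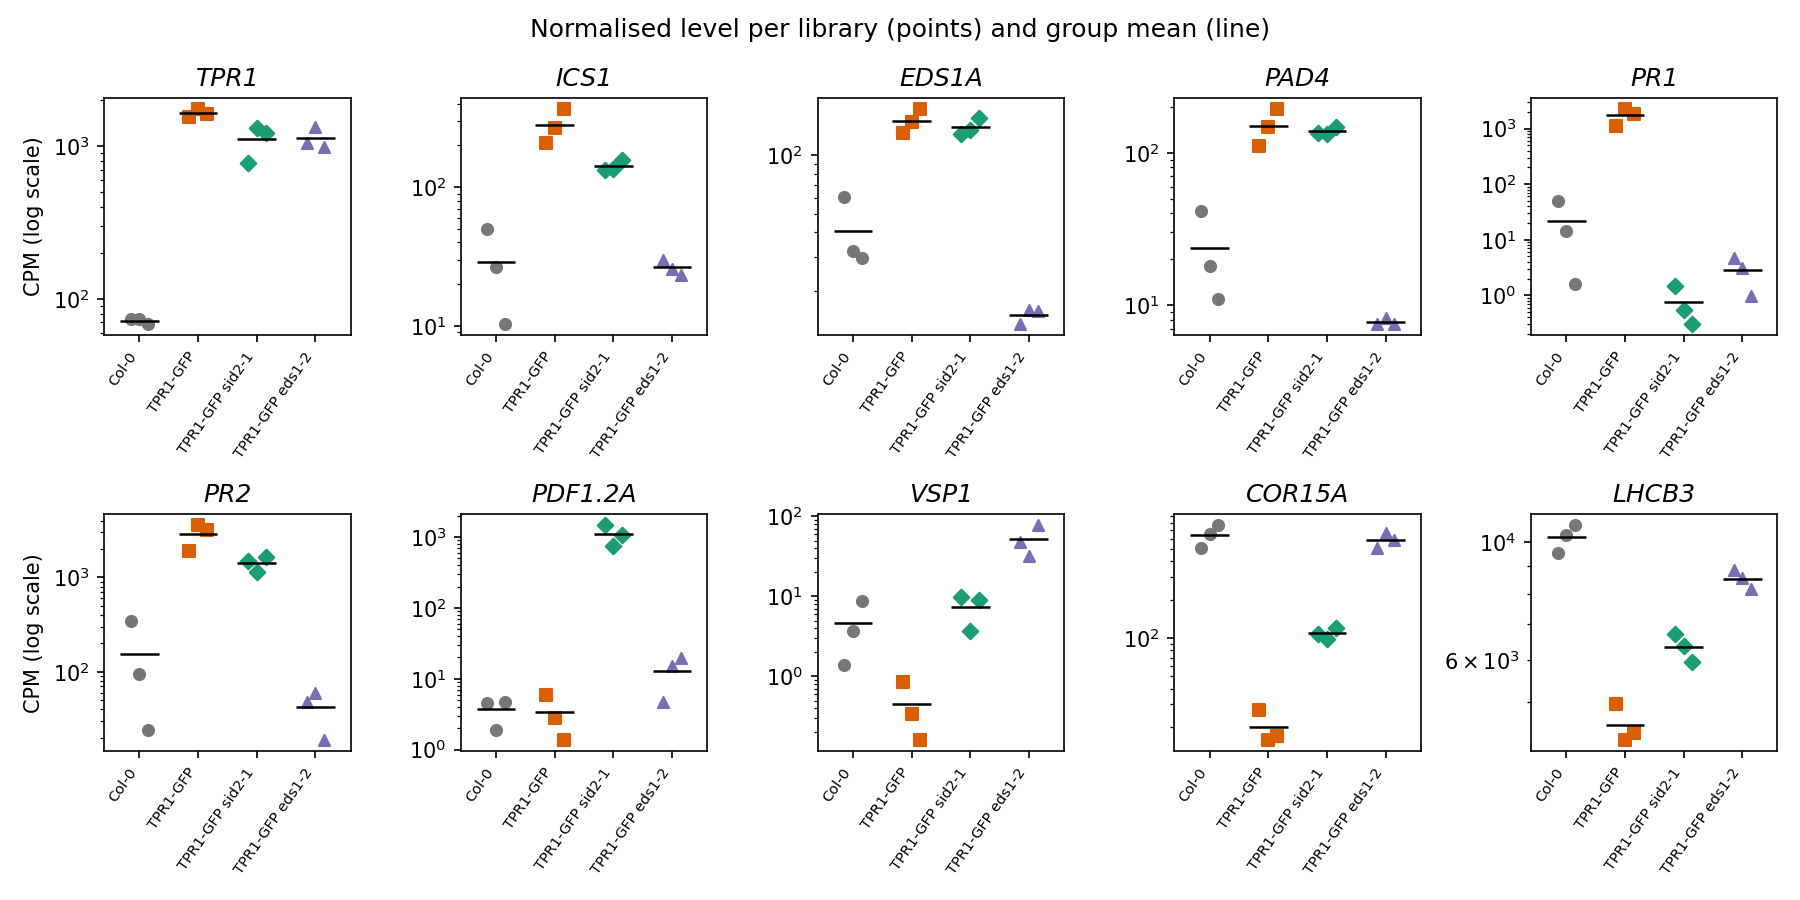
Normalised level of *TPR1*, *ICS1*, *EDS1A*, *PAD4*, *PR1*, *PR2*, *PDF1.2A*, *VSP1*, *COR15A* and *LHCB3* in each of the 12 libraries, with group means as lines.

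In TPR1-GFP against Col-0 (n = 3 and 3), *TPR1* rose 22.7-fold (log2 change 4.51, SE 0.20, adjusted p = 2.39e-07). Genes of SA synthesis and response rose with it. *ICS1* rose 9.73-fold (log2 3.28, SE 0.44), and *PBS3*, whose enzyme joins isochorismate to glutamate on the way to SA, rose 16.8-fold (log2 4.07, SE 0.42). The pathogenesis-related gene *PR1* went from a mean of 21.7 CPM (SD 24.7) to 1740 CPM (SD 598), a log2 change of 6.33 (SE 0.99, adjusted p = 0.000344). *PR2*, a glucanase gene, rose by 4.22 log2 units (SE 0.80) and *PR5*, which encodes a thaumatin-like protein, rose 12.1-fold. *EDS1A* rose by 1.88 (SE 0.24), *EDS1B* by 1.63 (SE 0.38), and the genes of the EDS1 partners *PAD4* and *SAG101* by 2.68 (SE 0.39) and 1.57 (SE 0.18). *FMO1*, which makes the mobile immune signal N-hydroxypipecolic acid, rose 82.1-fold (log2 6.36, SE 0.71), while its pathway partner *ALD1* had a log2 change of 1.86 (SE 0.89) with adjusted p = 0.0968.

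Across the SA synthesis list all 6 genes were higher in TPR1-GFP, among them *EDS5* and *CBP60G* (median log2 change 3.24, camera adjusted p = 2.96e-06, and adjusted p = 0.26 with an estimated correlation). All 22 SA response genes were higher, with *PR1*, *PR5*, *WRKY18* and *WRKY46* as examples (median 2.91, camera adjusted p = 7.47e-10, and adjusted p = 0.269 with an estimated correlation). In the N-hydroxypipecolic acid pathway 3 of 4 genes were higher (median 2.66, camera adjusted p = 0.0408, and adjusted p = 0.41 with an estimated correlation). All 9 genes of the EDS1 family and helper immune receptors were higher, among them *ADR1-L2* by 1.40 (SE 0.16) and *ADR1* (median 1.57, camera adjusted p = 2.53e-06, and adjusted p = 0.269 with an estimated correlation). Of 10 sensor receptor genes 9 were higher, including *SNC1* by 0.78 (SE 0.13) and *RPP4* by 0.95 (SE 0.16), with a median of 0.54 (camera adjusted p = 0.00692, and adjusted p = 0.472 with an estimated correlation). Cysteine-rich receptor-like kinases, a family of cell-surface kinases, were higher in 13 of 14 cases, with *CRK13* up 29.4-fold (log2 4.88, SE 0.33) beside *CRK23* and *CRK39* (median 2.84, camera adjusted p = 2.53e-06, and adjusted p = 0.269 with an estimated correlation).

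Receptors and signalling genes of pattern-triggered immunity counted 13 higher and 2 lower of 15, with *FRK1* up 45.0-fold (log2 5.49, SE 0.52) and *BIK1* by 1.38 (SE 0.14) (median 1.32, camera adjusted p = 2.68e-05, and adjusted p = 0.322 with an estimated correlation). In the camalexin and indole glucosinolate list 7 of 11 were higher, such as *CYP71A12*, up 24.4-fold (log2 4.61, SE 0.30), and *MYB51* and *CYP79B2* (median 0.91, camera adjusted p = 0.00142, and adjusted p = 0.41 with an estimated correlation). All 12 genes of folding and secretion in the endoplasmic reticulum were higher, for example *SDF2* by 1.34 (SE 0.15), *CRT3* by 2.07 (SE 0.29) and *BZIP60* (median 1.35, camera adjusted p = 2.96e-06, and adjusted p = 0.366 with an estimated correlation). Of 7 senescence genes 4 were higher, with *SAG13* up 30.2-fold (log2 4.92, SE 0.47) and *SAG21* by 2.38 (SE 0.20) (median 1.66, camera adjusted p = 0.00142, and adjusted p = 0.269 with an estimated correlation).

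Most genes of photosynthesis fell in TPR1-GFP. The photosystem II subunit gene *PSBO1* went from 7141 CPM (SD 319) to 3347 CPM (SD 140), a log2 change of −1.09 (SE 0.08), and the antenna gene *LHCB3* changed by −1.17 (SE 0.09). Of 25 photosynthesis genes 22 were lower, or 24 adjusted over the list alone (camera adjusted p = 3.29e-15, and adjusted p = 0.26 with an estimated correlation). All 11 cell-cycle genes were lower, among them the mitotic kinase gene *CDKB2;1* at −1.99 (SE 0.31) and the cytokinesis gene *KNOLLE* at −2.12 (SE 0.42) (median −2.07, camera adjusted p = 0.000354, and adjusted p = 0.41 with an estimated correlation). In the abscisic acid and cold list 9 were lower and 1 higher of 11. *COR15A*, which protects membranes in the cold, fell 32.4-fold (log2 −5.02, SE 0.24) and *RD29A* fell 23.3-fold (log2 −4.54, SE 0.36) (median −1.60, camera adjusted p = 9.81e-09, and adjusted p = 0.26 with an estimated correlation). Within the TOPLESS family only *TPR1* was higher, while *TPR3* fell 8.01-fold (log2 −3.00, SE 0.16), *TPR2* changed by −1.21 (SE 0.15) and *TPL* by −0.81 (SE 0.20).

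Other lists did not pass the camera test in TPR1-GFP against Col-0. *DND1* and *DND2* encode ion channels that hold back defence and are reported TPR1 targets. *DND1* had a log2 change of 0.07 (adjusted p = 0.589) and *DND2* rose by 0.58 (SE 0.13, adjusted p = 0.00298), with camera adjusted p = 0.457 for the pair. The MYC branch of jasmonate responses held 7 higher and 3 lower of 18, where *AOS* and *AOC2* of jasmonate synthesis changed by −1.36 (SE 0.18) and −1.58 (SE 0.19) while *LOX4* rose by 1.95 (SE 0.23). Of 7 genes in the ERF branch 3 were higher, including the chitinase gene *CHI-B* by 2.44 (SE 0.47). Auxin and cell expansion genes had 1 higher and 7 lower of 14, or 8 lower adjusted over the list alone, with *IAA29* lower at −3.45 (SE 0.56) and *EXPA1* higher by 1.73 (SE 0.29). Of 6 heat-shock genes 3 were higher and 1 lower, or 5 and 1 adjusted over the list alone, with *HSP90.1* higher by 2.57 (SE 0.36) and *HSP18.2* lower at −1.57 (SE 0.39). Clock genes had 5 higher and 1 lower of 13, among them *RVE8*, *CCA1* and *LHY*. Markers of other organs and cell types were measured too: 3 of 8 epidermis, guard-cell and trichome genes were lower, including *KAT1* at −1.18 (SE 0.18) and *ATML1* at −0.90 (SE 0.19). Of 7 vascular genes *APL* was higher by 0.59 (SE 0.15) and *CESA7* lower at −0.98 (SE 0.23), and the flowering gene *SOC1* was higher by 0.92 (SE 0.19). None of the 3 root genes was in the table, and the floral list of 3 measured genes had a median of −0.21, a mean of −0.28 and a test direction up (camera adjusted p = 0.98).

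The largest rises included *AT1G17615*, at least 44.1-fold, *AT1G29090*, at least 43.8-fold, and *AT1G67635*, at least 35.7-fold, each without a single count in Col-0. *AT2G44240* had 1 count in Col-0, giving a ratio of 693 with a counting interval of 124 to 27420. Among the largest falls *MRD1* dropped 101-fold (log2 −6.66, SE 0.22), and the myrosinase-binding gene *MBP1* changed by −9.25 (SE 0.91), although its Col-0 level was uneven at 239 CPM (SD 233). The xyloglucan enzyme gene *XTH31* fell 53.0-fold (log2 −5.73, SE 0.54). By the edgeR quasi-likelihood test 5192 genes were higher and 4979 lower, 10171 of the genes tested, and of these 2259 and 1905 moved at least 1 log2 unit. The split depends on the scaling, with 8349 higher and 3098 lower without scaling beyond the library total, and 44.2% of calls higher under upper-quartile scaling against 51.1% here. The 3 and 3 libraries did not overlap for 61.1% of all genes, where chance gives 10%. The authors' deposited columns call 5310 higher and 4931 lower, and 10006 calls are shared in the same direction.

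**Figure D3:**
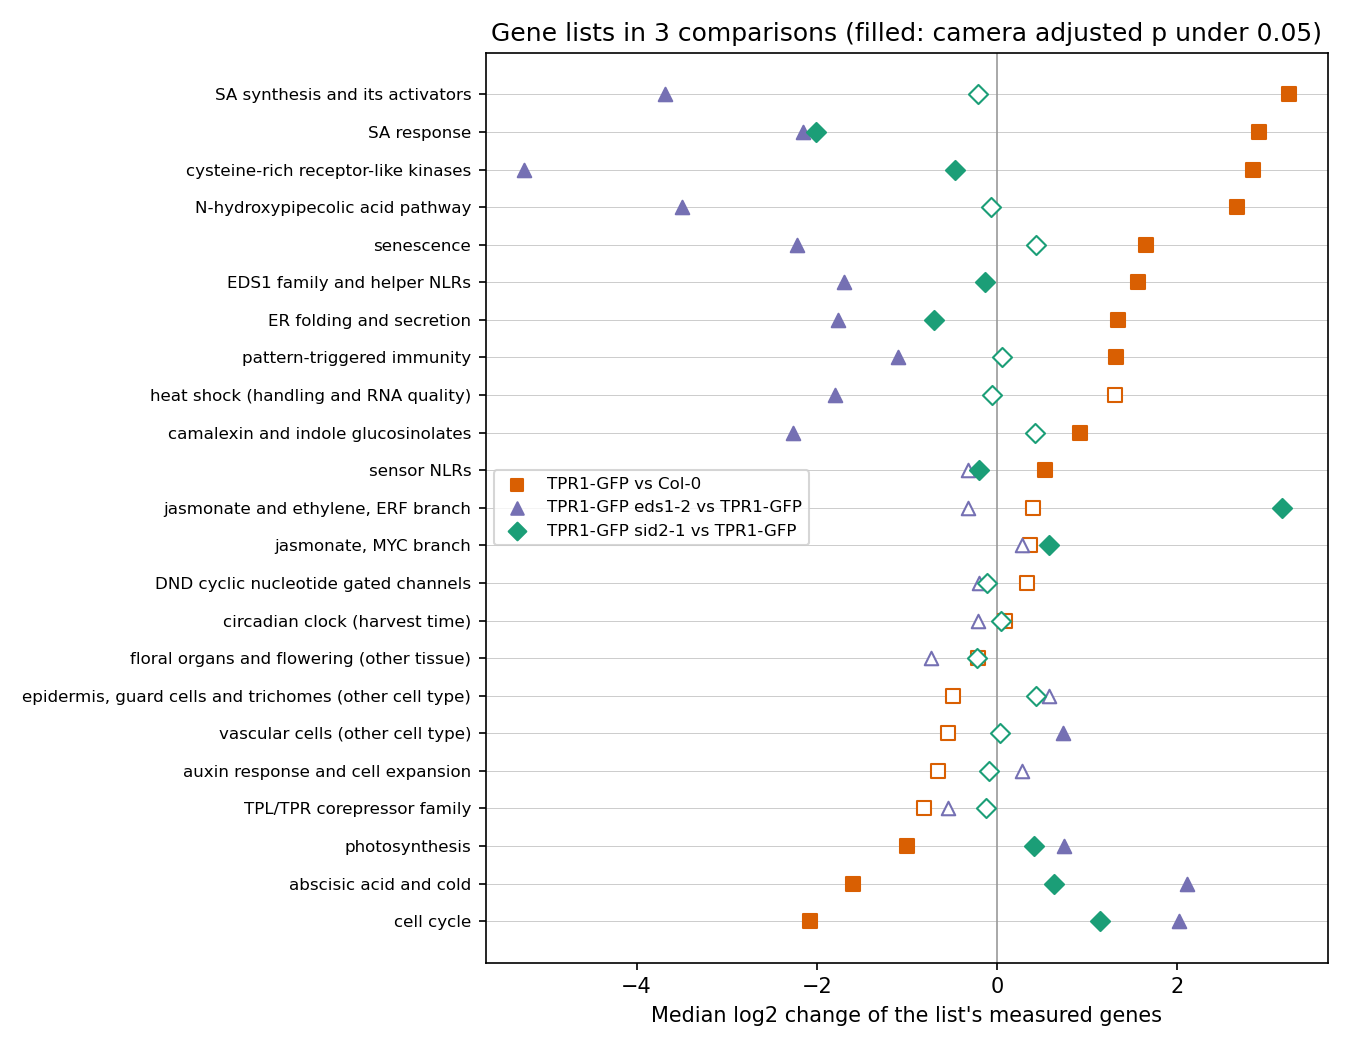
Median log2 change of each gene list in 3 comparisons, with 3 libraries per genotype. Filled symbols passed the camera test at adjusted p under 0.05.

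With eds1-2 in the background (TPR1-GFP eds1-2 against TPR1-GFP, n = 3 and 3), *ICS1* fell 10.6-fold (log2 −3.41, SE 0.44, adjusted p = 0.000105) and *EDS1A* fell 9.97-fold (log2 −3.32, SE 0.25). *PR1* went from 1740 CPM to 2.91 CPM (SD 1.85), a 596-fold fall (log2 −9.22, SE 1.15), and *PR2* changed by −6.09 log2 units (SE 0.88) and *PR5* by −4.15 (SE 0.29). *PAD4* fell 19.5-fold (log2 −4.28, SE 0.42), *SAG101* changed by −1.33 (SE 0.17) and *EDS1B* by −2.68 (SE 0.41), and *FMO1* fell 189-fold (log2 −7.56, SE 0.81). *CBP60G* and *SARD1* encode transcription factors that switch on *ICS1*, and they changed by −3.97 (SE 0.29) and −4.27 (SE 0.48). *TPR1* itself was lower at −0.54 (SE 0.17, adjusted p = 0.0199). That call is lost without TPR1-GFP replicate 2 (adjusted p = 0.0659), TPR1-GFP eds1-2 replicate 1 (0.0664) or TPR1-GFP eds1-2 replicate 3 (0.0801).

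In the eds1-2 line 5 of 6 SA synthesis genes were lower than in TPR1-GFP (median −3.69, camera adjusted p = 6.07e-06, and adjusted p = 0.235 with an estimated correlation). For SA response 15 of 22 were lower, or 18 adjusted over the list alone, with *WRKY53* at −3.30 (SE 0.27), *WRKY46* and *PNP-A* as examples (median −2.15, camera adjusted p = 7.16e-07, and adjusted p = 0.394 with an estimated correlation). All 4 genes of the N-hydroxypipecolic acid pathway were lower, *ALD1* at −4.43 (SE 1.15) (median −3.50, camera adjusted p = 0.0356, and adjusted p = 0.401 with an estimated correlation). All 9 EDS1 family and helper receptor genes were lower (median −1.69, camera adjusted p = 2.03e-07, and adjusted p = 0.235 with an estimated correlation), among them *ADR1-L2* and *ADR1*. This list holds *EDS1A*, which eds1-2 affects, and *EDS1B* and *PAD4*, which also lie in the stretch around *EDS1* examined below. Lower counts of these genes can come from the allele or linked sequence, and the list test does not separate that from a wider response. Sensor receptors had 5 lower of 10, or 6 adjusted over the list alone, including *SNC1* at −0.54 (SE 0.13) and *RPP4* at −0.71 (SE 0.16) (camera adjusted p = 0.0838). Cysteine-rich kinases were lower in 13 of 14 cases, or 14 adjusted over the list alone, with *CRK4*, which lies near *EDS1*, down 1641-fold (log2 −10.68, SE 1.05) and *CRK13* down 61.0-fold (log2 −5.93, SE 0.35) (median −5.25, camera adjusted p = 1.19e-10, and adjusted p = 0.235 with an estimated correlation).

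Pattern-triggered immunity counted 2 higher and 11 lower of 15, with *SOBIR1*, *BIK1* and *BIR1* among the falls (median −1.10, camera adjusted p = 0.000106, and adjusted p = 0.346 with an estimated correlation). In the camalexin and indole glucosinolate list 9 of 11 were lower, led by *CYP71A12*, down 57.7-fold (log2 −5.85, SE 0.35), *MYB51* and *CYP81F2* (median −2.26, camera adjusted p = 6.69e-06, and adjusted p = 0.235 with an estimated correlation). All 12 endoplasmic reticulum genes were lower, such as *SDF2* at −1.55 (SE 0.15), *CRT3* and *CRT1A* (median −1.77, camera adjusted p = 7.52e-09, and adjusted p = 0.235 with an estimated correlation). Of 7 senescence genes 6 were lower, or 7 adjusted over the list alone, with *SAG13* down 41.5-fold (log2 −5.38, SE 0.48) and *SAG21* (median −2.22, camera adjusted p = 5.71e-05, and adjusted p = 0.235 with an estimated correlation). Heat-shock genes had 5 lower of 6 while *HSP18.2* was higher (median −1.80, camera adjusted p = 0.0371, and adjusted p = 0.401 with an estimated correlation).

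Most photosynthesis, cell-cycle and cold genes moved the other way in the eds1-2 line. *COR15A* rose 29.3-fold (log2 4.87, SE 0.24) to 584 CPM (SD 78.7), next to 645 CPM (SD 130) in Col-0, and *KIN2* rose by 2.59 (SE 0.16). The abscisic acid and cold list had 9 higher and 1 lower of 11 (camera adjusted p = 7.35e-08, and adjusted p = 0.235 with an estimated correlation). Of 25 photosynthesis genes 21 were higher, or 22 adjusted over the list alone, with *PSBO1* up by 0.87 (SE 0.08) and *LHCB6* by 0.98 (SE 0.10) (median 0.75, camera adjusted p = 4.62e-10, and adjusted p = 0.235 with an estimated correlation). Cell-cycle genes were higher in 10 of 11 cases, including *CDKB2;1* by 2.28 (SE 0.30) and *CYCD3;1* by 2.61 (SE 0.44) (median 2.02, camera adjusted p = 0.000352, and adjusted p = 0.401 with an estimated correlation). Vascular markers were higher in 5 of 7 cases, with the phloem sucrose transporter gene *SUC2* up by 0.70 (SE 0.12) and *CESA7* by 1.27 (SE 0.23) (median 0.73, camera adjusted p = 0.0308, and adjusted p = 0.401 with an estimated correlation).

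Lists that did not pass the camera test against TPR1-GFP also held single calls. Epidermis, guard-cell and trichome genes had 5 higher of 8, or 6 adjusted over the list alone, such as *TRY* and *GC1*, with camera adjusted p = 0.0731. The floral organ gene *AG* rose 9.88-fold (log2 3.30, SE 0.43) to 2.15 CPM, and that list of 3 had a median of −0.73, a mean of 0.59 and a test direction up. In the MYC branch *VSP1*, a vegetative storage protein gene, rose 115-fold (log2 6.84, SE 0.75) and *AOS* by 1.48 (SE 0.18), while *LOX4* changed by −1.95 (SE 0.23), for 5 higher and 3 lower of 18. The ERF branch split into 2 higher and 2 lower of 7, with a median of −0.32 and a mean of 0.00. Auxin and cell expansion genes split into 4 and 4 of 14, including *EXPA4* at 1.02 (SE 0.21), and 4 of 13 clock genes were lower, with *RVE1* at −2.51 (SE 0.28). *DND1* had a log2 change of 0.11 (adjusted p = 0.418), and *DND2* was lower at −0.50 (SE 0.13, adjusted p = 0.00723). In the TOPLESS family *TPL* changed by −1.20 (SE 0.20) and *TPR2* by −1.13 (SE 0.16).

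The largest rises in the eds1-2 line over TPR1-GFP were *AT3G44070*, which lies near *EDS1*, at least 489-fold, and *AT5G20750*, at least 244-fold, followed by genes of anthocyanin and fatty alcohol synthesis: *FAR8*, at least 175-fold, *UF3GT*, up 376-fold (log2 8.55, SE 0.41), and *LDOX*, up 257-fold (log2 8.01, SE 0.39). The triterpene synthase gene *LAS1* went from 18.9 CPM to 0, at least a 403-fold fall, and *ARI12* and *HIPP22* fell at least 216-fold and 202-fold. In all 4760 genes were higher and 5230 lower by the edgeR test, with 1937 and 1866 at least 1 log2 unit apart. Higher genes made up 47.7% of these calls, 32.6% without scaling and 59.7% under upper-quartile scaling, so which direction has more calls turns with the scaling. Libraries of the pair of lines did not overlap for 60.4% of genes (chance 10%). The authors' columns call 4658 and 5460, with 9797 calls shared in direction.

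With sid2-1 in the background (TPR1-GFP sid2-1 against TPR1-GFP, n = 3 and 3), most SA response genes fell while the genes of SA synthesis did not pass the test. *PR1* fell 2423-fold (log2 −11.24, SE 1.28, adjusted p = 0.00058) to 0.766 CPM (SD 0.610), and *WRKY38* had a single count in the sid2-1 line, a ratio of 1547 with a counting interval of 277 to 61130. *WRKY54* changed by −2.62 (SE 0.26), *NIMIN2*, a partner of the SA receptor NPR1, by −2.99 (SE 0.45), and *PR5* by −1.24 (SE 0.26). *ICS1* had a log2 change of −0.99 (SE 0.40, adjusted p = 0.114), and *PAD4* one of −0.12 (adjusted p = 0.837). *EDS1A* had a log2 change of −0.10 (adjusted p = 0.782), *EDS1B* changed by −2.24 (SE 0.39), and *FMO1* had 0.75 (adjusted p = 0.238). *TPR1* was lower at −0.57 (SE 0.17, adjusted p = 0.0433), a call lost without TPR1-GFP replicate 1 (adjusted p = 0.0506), replicate 2 (0.137) or replicate 3 (0.104), or without TPR1-GFP sid2-1 replicate 1 (0.0947) or replicate 3 (0.0605).

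Of 22 SA response genes 17 were lower in the sid2-1 line, or 18 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.16e-16, and adjusted p = 0.42 with an estimated correlation). None of 6 SA synthesis genes passed in either direction (median −0.21, camera adjusted p = 0.648), nor did any of 4 in the N-hydroxypipecolic acid pathway, where 1 was lower adjusted over the list alone (median −0.07). *PR2* stood at 1424 CPM (SD 243) next to 2893 CPM (SD 866) in TPR1-GFP, with a log2 change of −1.02 (adjusted p = 0.335). The ERF branch of jasmonate and ethylene defence rose in all 7 of its genes (camera adjusted p = 1.36e-11, and adjusted p = 0.0517 with an estimated correlation). The defensin gene *PDF1.2A* went from 3.37 CPM (SD 2.36) to 1102 CPM (SD 361), a 326-fold rise (log2 8.35, SE 0.70), and *PDF1.2B* rose 232-fold (log2 7.86, SE 0.55). *ORA59*, the transcription factor that drives these defensins, rose 8.97-fold (log2 3.17, SE 0.42). In the MYC branch 6 of 18 were higher, or 8 adjusted over the list alone, with *VSP1* up 16.2-fold (log2 4.02, SE 0.77), *AOS* by 0.90 (SE 0.18) and *AOC2* (median 0.58, camera adjusted p = 0.000166, and adjusted p = 0.788 with an estimated correlation).

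Photosynthesis genes were higher than in TPR1-GFP in 15 of 25 cases, or 17 adjusted over the list alone, *PSBO1* by 0.47 (SE 0.08) and *LHCA2* by 0.49 (SE 0.08) (median 0.41, camera adjusted p = 7.83e-07, and adjusted p = 0.788 with an estimated correlation). *COR15A* rose 5.44-fold (log2 2.44, SE 0.22), with 3 higher and 1 lower of 11 abscisic acid and cold genes, the lower being *RD29B* (median 0.63, camera adjusted p = 0.0249, and adjusted p = 0.788 with an estimated correlation). In the cell-cycle list 1 of 11 was higher, or 6 adjusted over the list alone (median 1.15, camera adjusted p = 0.0253, and adjusted p = 0.788 with an estimated correlation). Of 12 endoplasmic reticulum genes 8 were lower, or 9 adjusted over the list alone, including *SDF2* at −0.70 (SE 0.15) (median −0.70, camera adjusted p = 3.43e-05, and adjusted p = 0.788 with an estimated correlation). Small shifts passed the camera test in the EDS1 family with 3 lower of 9, sensor receptors with 1 of 10 (both camera adjusted p = 0.0478) and cysteine-rich kinases with 2 of 14 (camera adjusted p = 0.0347), each with adjusted p = 0.788 with an estimated correlation.

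The other lists did not pass in the sid2-1 line against TPR1-GFP. Pattern-triggered immunity had 2 higher and 3 lower of 15, *PEPR1* among the higher, with a median of 0.05 and a mean of −0.07. Camalexin and indole glucosinolate genes had 3 higher of 11, or 4 adjusted over the list alone (camera adjusted p = 0.0999). Of 13 clock genes 2 were higher, *LUX* by 1.03 (SE 0.17) and *PRR5* by 0.74 (SE 0.14), and 3 were lower, including *LHY* at −1.37 (SE 0.20), or 2 and 4 adjusted over the list alone, with a median of 0.05 and a mean of −0.02. Auxin genes had 2 higher of 14 (median −0.09, mean 0.16, test direction up) and epidermis genes 2 higher of 8. Senescence had none of 7, or 2 higher and 1 lower adjusted over the list alone, and heat shock had none of 6 (median −0.05, mean 0.00). No vascular or floral marker passed. *DND1* had a log2 change of 0.10 (adjusted p = 0.524) and *DND2* one of −0.32 (adjusted p = 0.110). In the TOPLESS family *TPR1* alone was lower, or 1 higher and 1 lower adjusted over the list alone.

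Beyond these lists, *DIN11* rose 105-fold (log2 6.72, SE 0.61), *PDF1.2C* rose 1242-fold (log2 10.28, SE 0.72) and *PDF1.3* 285-fold (log2 8.16, SE 0.44). *ARD3* went from 13.8 CPM to 0, at least a 336-fold fall. *AT3G47050* changed by −5.82 (SE 0.61) and *SCPL16* by −4.17 (SE 0.56). By edgeR 1832 genes were higher and 1347 lower, with 606 and 301 at least 1 log2 unit apart. Higher genes made up 57.6% of these calls, 62.9% under upper-quartile scaling but 38.1% without scaling, where 2293 were lower. Of all genes 39.9% had libraries that did not overlap (chance 10%). These counts hang on single libraries. Higher genes numbered 727 without TPR1-GFP replicate 2, 854 without replicate 3, 937 without TPR1-GFP sid2-1 replicate 1 and 936 without replicate 2. Lower genes numbered 445 and 475 without TPR1-GFP replicates 2 and 3, and 639, 498 and 798 without TPR1-GFP sid2-1 replicates 1, 2 and 3. Without TPR1-GFP replicate 1, in contrast, 2045 were higher and 1598 lower. On component 1 of the principal component analysis that library lay at 54.53, within the 45.66 to 58.79 of the sid2-1 libraries. TPR1-GFP replicates 2 and 3 lay at 87.94 and 90.68. The authors' columns call 1896 and 1613, with 3077 shared in direction.

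The TPR1-GFP response was largely absent from the eds1-2 line and mostly present in the sid2-1 line. *CRK13*, for example, stood at 91.5 CPM in TPR1-GFP, 103 CPM in the sid2-1 line and 1.49 CPM in the eds1-2 line, beside 3.15 CPM in Col-0. Of 5192 genes higher in TPR1-GFP, 951 (18.3%) were also higher than Col-0 in the eds1-2 line and 3376 (65.0%) in the sid2-1 line, where independent lists would give 492 and 1149. Among the 2259 of them that rose at least 1 log2 unit, the median share of the change kept was 0.187 in the eds1-2 line and 0.818 in the sid2-1 line. Of 4979 lower genes, such as *COR15A*, 656 (13.2%) stayed lower in the eds1-2 line and 2901 (58.3%) in the sid2-1 line, against 399 and 992 for independent lists, with median shares kept of 0.156 and 0.581 among the 1905 that fell at least 1 log2 unit. The 951 became 620 without Col-0 replicate 2, and the 0.187 became 0.282 without Col-0 replicate 1 and 0.103 without TPR1-GFP eds1-2 replicate 2. The 656 became 380 without Col-0 replicate 2, 424 and 372 without TPR1-GFP eds1-2 replicates 2 and 3, the 0.156 became 0.0933 without replicate 2 of that line, and the 2901 became 1901 without Col-0 replicate 3. Both sets of comparisons share the Col-0 libraries. No line had eds1-2 or sid2-1 without the transgene, so the shares kept also hold the effect of each mutation alone. Log2 changes from Col-0 in TPR1-GFP and in the eds1-2 line had r = 0.240 and the same sign in 60.6% of genes. These lay below the 0.51 and 66.9% of simulated unchanged groups that share a simulated control, while the covariance of 0.231 lay above the simulated 0.0327. For TPR1-GFP and the sid2-1 line the changes had r = 0.847 and 82.2%, where simulated groups gave 0.516 and 67.1%. No real Col-0 library enters the simulated values.

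Against TPR1-GFP, 1033 genes were lower in both double lines, *PR1*, *EDS1B* and *SDF2* among them, and 1315 were higher in both, such as *COR15A*, *VSP1* and *PSBO1*. Independent lists would give 373 and 462. Log2 changes in the eds1-2 and sid2-1 lines correlated at r = 0.478 over all genes. Simulated unchanged groups that share a simulated control gave 0.483, but the observed covariance of 0.377 lay above the simulated 0.0302. Deviations of the real TPR1-GFP libraries that many genes share are not part of the simulated values. The 1033 became 337 and 346 without TPR1-GFP replicates 2 and 3, and 511, 400 and 593 without TPR1-GFP sid2-1 replicates 1, 2 and 3. In the same order the 1315 became 490, 559, 720, 696 and 839. Without TPR1-GFP replicate 1 the counts rose to 1346 and 1630.

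Set directly against each other (TPR1-GFP sid2-1 against TPR1-GFP eds1-2, n = 3 and 3), the double lines differed in *FMO1* by 316-fold (log2 8.30, SE 0.80), in *PAD4* by 4.16 log2 units, in *ICS1* by 2.43 (SE 0.43) and in *EDS1A* by 3.21, all higher in the sid2-1 line. *PR2* was higher there by 5.07 and *PR5* by 2.90, whereas *PR1* had −2.02 (adjusted p = 0.214) and *TPR1* −0.03 (adjusted p = 0.92). *WRKY54* was lower in the sid2-1 line at −2.06 (SE 0.25). Genes without any count in the eds1-2 line led the rises, *ARI12* at least 332-fold, *AT3G46080* at least 212-fold and *AT1G53620* at least 158-fold, while *DFR* fell 304-fold (log2 −8.25, SE 0.44) and *LDOX* changed by −8.64 (SE 0.42). SA synthesis had 5 higher of 6 (camera adjusted p = 4.46e-07), cysteine-rich kinases 12 of 14 (4.99e-12), camalexin and indole glucosinolates 9 of 11 (3.72e-10), the ERF branch 7 of 7 (4.53e-07), senescence 7 of 7 (6.43e-08) and the EDS1 family 7 of 9 (6.07e-07). With an estimated correlation, adjusted p ran for these from 0.0704 to 0.211. The limit given above for *EDS1A*, *EDS1B* and *PAD4* holds for the EDS1 family here too. Also higher in the sid2-1 line were pattern-triggered immunity in 10 of 15 (camera adjusted p = 1.16e-06), endoplasmic reticulum genes in 12 of 12 (8.15e-06), N-hydroxypipecolic acid genes in 2 of 4 (0.0375) and heat shock with 5 higher and 1 lower of 6 (0.0121). Lower there were photosynthesis in 17 of 25 (median −0.37, 1.67e-05), cell cycle in 5 of 11, or 7 adjusted over the list alone (0.00778), and vascular markers in 4 of 7 (0.0137). For these 7 lists adjusted p with an estimated correlation ran from 0.211 to 0.486. Cold genes were lower in 7 of 11 cases, or 8 adjusted over the list alone (camera adjusted p = 2.96e-07, and adjusted p = 0.128 with an estimated correlation). SA response split into 9 higher and 8 lower of 22, or 10 and 9 adjusted over the list alone (camera adjusted p = 0.604). Calls numbered 3687 higher and 2813 lower, 56.7% higher against 43.2% under upper-quartile scaling and 70.04% without scaling. The 2813 became 1777 without TPR1-GFP sid2-1 replicate 2, and 1862 and 1856 without TPR1-GFP eds1-2 replicates 1 and 3.

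Next to Col-0 the eds1-2 line (n = 3 and 3) kept *TPR1* 15.6-fold higher (log2 3.96), while *ICS1* had a log2 change of −0.13 (adjusted p = 0.857) and *EDS1A* was lower at −1.44. *WRKY54* was higher by 1.45 and *VSP1* by 3.48, and *WRKY33* was lower at −1.08. Cysteine-rich kinases were lower in 7 of 14 cases, or 11 adjusted over the list alone (median −1.88, camera adjusted p = 0.00013, and adjusted p = 0.948 with an estimated correlation). The TOPLESS family had 2 higher and 3 lower of 5, *TPL* at −2.01 and *TPR3* at −2.98, and the MYC branch 6 higher and 1 lower of 18, *OPR3* by 1.39 (SE 0.15) and *LOX3* by 1.28 (SE 0.16). Both had camera adjusted p = 0.00825, and adjusted p = 0.948 with an estimated correlation. In all 1789 genes were higher and 1514 lower, the latter 938 without scaling. Higher genes made up 54.2% of these calls, 70.8% without scaling and 63.8% under upper-quartile scaling. Without Col-0 replicate 2 the counts were 1165 and 938, and the lower genes were 980 and 841 without TPR1-GFP eds1-2 replicates 2 and 3.

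Next to Col-0 the sid2-1 line (n = 3 and 3) kept *TPR1* 15.3-fold higher (log2 3.94) and *ICS1* higher by 2.30, with *TPR3* lower at −2.54. Here 4178 genes were higher and 3762 lower, 52.6% higher against 76.5% without scaling, where 1910 were lower, and 47.2% under upper-quartile scaling. SA synthesis was higher in 6 of 6 cases (camera adjusted p = 3.44e-07), pattern-triggered immunity in 13 of 15, or 13 higher and 1 lower adjusted over the list alone (3.33e-07), the ERF branch in 7 of 7 (6.07e-08), and photosynthesis was lower in 20 of 25, or 23 adjusted over the list alone (3.79e-09). With an estimated correlation, adjusted p for these ran from 0.139 to 0.261. The EDS1 family was higher in 8 of 9 (camera adjusted p = 1.50e-05), cysteine-rich kinases in 10 of 14, or 11 adjusted over the list alone (1.50e-05), camalexin and indole glucosinolates in 9 of 11 (8.85e-07) and N-hydroxypipecolic acid genes in 2 of 4 (0.0451). Senescence was higher in 6 of 7, or 7 adjusted over the list alone (7.70e-06), endoplasmic reticulum genes in 7 of 12, or 10 adjusted over the list alone (0.00559), and the MYC branch had 9 higher and 1 lower of 18, or 10 and 3 adjusted over the list alone (0.00019). Cell-cycle genes were lower in 4 of 11 (0.00831) and cold genes in 6 of 11, or 7 lower and 1 higher adjusted over the list alone (5.36e-08). For these 9 lists adjusted p with an estimated correlation ran from 0.139 to 0.476. SA response had 8 higher and 2 lower of 22 (camera adjusted p = 0.0553).

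Genes near *EDS1* on chromosome 3 stood out in the eds1-2 line. *EDS1A*, *EDS1B*, *PAD4*, *CRK4*, *LAS1*, *FAR8*, *AT3G44070* and *AT3G46080*, named above, lie in the region from AT3G40000 to AT3G55000. *AT3G43690*, chosen after its values were seen, and *AT3G47675* had no count in any of its 3 libraries, where Col-0 had 1033 and 587 counts and the sid2-1 line 481 and 588. Of 19 genes without a count in the eds1-2 line and with at least 100 expected from the other genotypes, 7 lie in this region and 12 elsewhere. Among the 7, *LAS1* and *AT3G46080* had few counts in Col-0 as well, 9 and 13, against 1656 and 578 in TPR1-GFP. Of 838 tested genes between locus codes AT3G40000 and AT3G55000, 139 (16.6%) differed in the eds1-2 line from all 3 other genotypes in the same direction, against 1021 of 18039 elsewhere (5.66%), an odds ratio of 3.31 (95% interval 2.71 to 4.03, Fisher exact p = 9.38e-28). The excess lay in lower genes, 106 with an odds ratio of 5.15, while 33 higher genes gave 1.36 (Fisher exact p = 0.0955). In the narrower stretch AT3G46000 to AT3G50000 that odds ratio of 3.31 was 3.24. The test of genes that differ from all 3 other genotypes was not the planned one, and Fisher's test takes neighbouring genes as independent. In the planned test, calls of the eds1-2 line against TPR1-GFP alone had an odds ratio of 1.41 in the region, and 1.22 (Fisher exact p = 0.111) in the narrower stretch. In the sid2-1 line the odds ratio was 0.86 (Fisher exact p = 0.131). Of 373 windows of 50 genes, 5 had at least 25% such genes and all 5 began in the region, while the highest elsewhere was 22%.

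**Figure D4:**
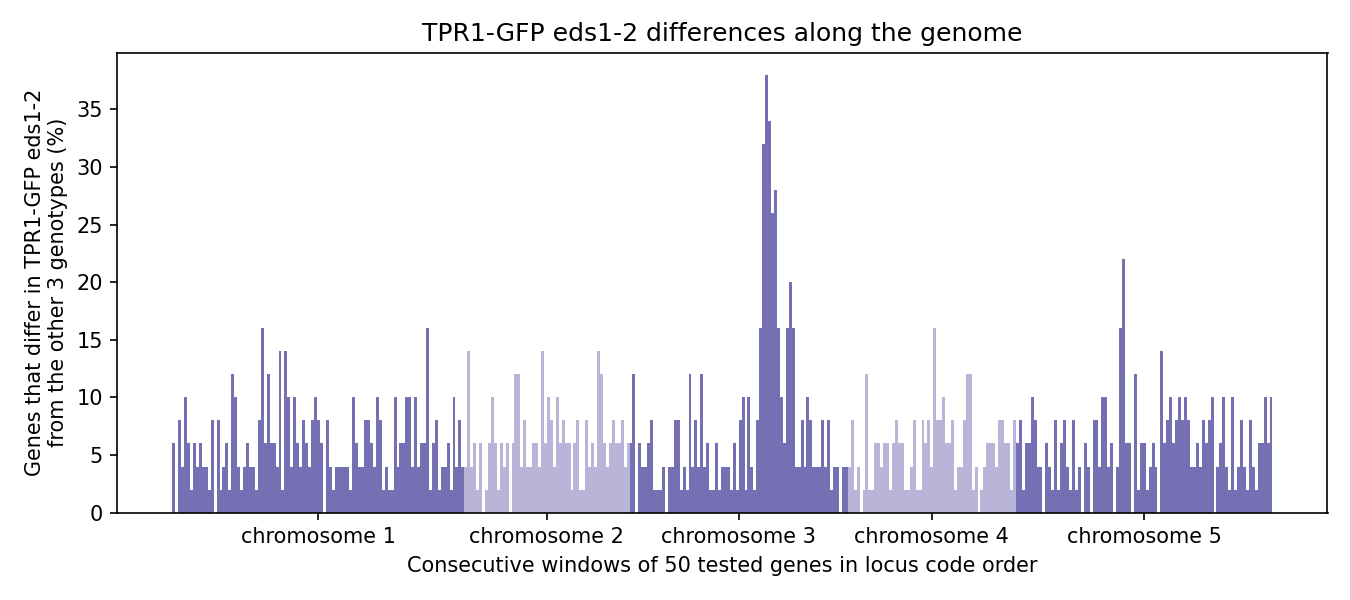
Share of genes in consecutive windows of 50 that differ in TPR1-GFP eds1-2 from the other 3 genotypes, along the 5 chromosomes.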

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

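The splits of the libraries were planned, while the tests weighed against the genes around *EDS1*, the defensins and the kept response were chosen only after these results were seen. In each comparison of genotypes the real grouping was 1 of 10 splits with at least as many called genes. The real counts of 10171, 9990, 3179, 6500, 3303 and 7940 stood against a highest other count of 0 each time, and 10 splits are too few for a share under 0.05. Every other split puts both genotypes in each group, so the real difference widens the spread within groups. The 0 is therefore no measure of false calls.

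The eds1-2 allele came from the accession Ler and was brought into Col-0, so Ler sequence may still surround it. Linked sequence of another accession fits the odds ratio of 3.31 for genes near *EDS1* that differ in the eds1-2 line, and it fits the lean towards lower genes, since reads that differ from the reference can be lost in alignment. A response to the loss of EDS1 spread evenly over the genome is hard to square with an interval that begins at 2.71. Low depth of the eds1-2 libraries is ruled out for *AT3G43690*, which had no count where 578 were expected. Lost alignment was not separated from a true lower level of the Ler alleles, and the lack of counts of *LAS1* and *AT3G46080*, low in Col-0 as well, does not separate linkage from the lost TPR1-GFP response.

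Summed transcripts of 4 defensin genes stood at 2580 CPM in the sid2-1 line, 18.25 CPM in the eds1-2 line and 6.998 CPM in TPR1-GFP, although both double lines had low *PR1*, and *PDF1.2A* alone was 1.95 log2 units above TPR1-GFP in the eds1-2 line (adjusted p = 0.0144, and 0.055, 0.0543 and 0.0623 without TPR1-GFP replicates 2 and 3 or TPR1-GFP eds1-2 replicate 3). A single sid2-1 library is excluded, because the lowest of the 3 had 39.0 times the *PDF1.2A* level of the highest of the 9 others. Reads shifted between near-identical copies could not raise that sum, which was higher by 8.53 log2 units over TPR1-GFP. *PDF1.2A* differed between the double lines by 6.40 log2 units. That difference does not exclude a low SA response as the cause, because the SA response was not equal in the 2 lines. *PR2* and *PR5* were higher in the sid2-1 line than in the eds1-2 line, while *WRKY54* was lower there. What drives *ORA59* and the defensins was not tested.

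The changes of TPR1-GFP from Col-0 were mostly absent from the eds1-2 line and mostly present in the sid2-1 line. A lower *TPR1* transcript level in the eds1-2 line does not account for this, since the lines differed by only −0.027 log2 units (SE 0.17) in *TPR1*. The scaling between libraries does not account for it either, because the median kept share of genes higher in TPR1-GFP still differed by 0.57 with no scaling beyond the library total. Protein levels of TPR1-GFP were not analysed here and could differ between the lines. The series holds no eds1-2 or sid2-1 plants without the transgene. The effect of each mutation alone can thus not be told from a change in the TPR1-GFP response. Part of the overlap may come from the shared controls, which with 3 libraries cannot be split into separate sets of 2, so the kept share of 0.818 rests on the same Col-0 libraries as the response itself.

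Changes from TPR1-GFP differed between the double lines for 6500 genes. Of these, 149 were lower in the eds1-2 line and higher in the sid2-1 line, and 27 were the reverse, where independent lists would give 508 and 340. Both changes are taken from the same TPR1-GFP libraries, which favours equal signs. Simulated unchanged groups had the same sign in 66.2% of genes, so the independent numbers are not the values for no change. Without TPR1-GFP replicates 2 and 3 the 149 became 60 and 91, and without TPR1-GFP sid2-1 replicates 1, 2 and 3 they became 73, 77 and 94. The 27 became 17, 8 and 8 without TPR1-GFP replicates 1, 2 and 3, then 9, 8 and 16 without TPR1-GFP sid2-1 replicates 1, 2 and 3, and 15 without TPR1-GFP eds1-2 replicate 3. The difference between the double lines was 3.20 log2 units for *MYB51*, 6.83 for *CYP71A12*, 5.25 for *PAD3* and 2.18 for *WRKY33*, all of indole metabolism and camalexin. It was 3.17 for *HEL* and 3.002 for *CHI-B*, which encode chitin-binding and chitin-degrading proteins. For *AT1G67635*, *AT3G61390* and *AT5G63225* the fit gave 9.17, 10.34 and 9.23 log2 units, which rest on 0, 0 and 1 counts in the eds1-2 line. By counting alone, the first was at least 63.6-fold and the next at least 145-fold higher in the sid2-1 line, and *AT5G63225* had a ratio of 804 with a counting interval of 144 to 31780.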

How the results depend on the processing

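No scaling beyond the library total and the families outside the lists were tests chosen only after the results were seen. Of 351 results past the threshold among the rule's genes selected for the text, 346 had 3 and 3 libraries that did not overlap. This is no independent support. The rule itself asked for libraries without overlap in the largest rises and falls, and for the smallest adjusted p within lists. With all 6 comparisons of the genes named after their values were seen added, 365 of 448 results passed. Of their 7789 alternative values 7447 kept direction and side of the threshold, 236 no longer passed, 66 newly passed and 40 changed sign.

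With only the 6 libraries of a comparison, eds1-2 against Col-0 had 1135 higher and 669 lower genes, and the kept genes of the eds1-2 line were 521 higher and 316 lower. At a threshold of 0.01, sid2-1 against TPR1-GFP had 592 and 319, sid2-1 against eds1-2 2346 and 1284, eds1-2 against Col-0 830 and 566, and sid2-1 against Col-0 2662 and 1928. Kept genes were then 412 and 2122 among the higher and 226 and 1500 among the lower for eds1-2 and sid2-1, and shared genes were 254 lower, 400 higher, 41 and 2 opposite. Without scaling, TPR1-GFP against Col-0 had 8349 higher and 3098 lower, with 72.9% of calls higher against 51.1%. Lower genes were 2293 for sid2-1 against TPR1-GFP, 938 for eds1-2 against Col-0 and 1910 for sid2-1 against Col-0, kept genes were 1433, 5371, 342 and 1440, and 1928 were lower in both. Upper-quartile scaling moved the higher share of calls in eds1-2 against TPR1-GFP to 59.7% from 47.7% and in sid2-1 against eds1-2 to 43.2% from 56.7%, with 0 calls opposite. With the replicate number as a block, 2656 of the 3179 calls of sid2-1 against TPR1-GFP were called again in the same direction. Of 138 list calls 60 passed with that block in place of 67. Lost were the N-hydroxypipecolic acid pathway in TPR1-GFP against Col-0 (adjusted p = 0.0704), eds1-2 against TPR1-GFP (0.0553), sid2-1 against eds1-2 (0.0662) and sid2-1 against Col-0 (0.0813), heat shock in eds1-2 against TPR1-GFP (0.0553), the EDS1 family and sensor receptors in sid2-1 against TPR1-GFP (both 0.0618) and the TOPLESS family in eds1-2 against Col-0 (0.0668). Camalexin and indole glucosinolates in eds1-2 against Col-0 passed newly (0.0483). With an estimated correlation 0 passed in each comparison. With fry 74 of 138 passed, and of the 67 past camera 58 passed fry as well. Fewer passed with fry than with camera only in sid2-1 against TPR1-GFP, 3 in place of 10, and in eds1-2 against Col-0, 1 in place of 3. The narrower region gave an odds ratio of 3.239 in place of 3.314 for genes that differ from the 3 other genotypes, and 1.216 in place of 1.411 for calls of eds1-2 against TPR1-GFP. List medians changed sign without scaling for floral genes in TPR1-GFP (0.04) and for pattern-triggered immunity (−0.03), clock (−0.03) and vascular genes (−0.05) in sid2-1 against TPR1-GFP, and under upper-quartile scaling for sensor receptors and *DND* channels (both −0.01) in sid2-1 against eds1-2. Pattern-triggered immunity in eds1-2 against Col-0, at −0.03, became 0.02 and 0.06.

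Leaving out libraries in turn gave 727 to 2045 higher and 445 to 1598 lower for sid2-1 against TPR1-GFP, 1777 to 2935 lower for sid2-1 against eds1-2, and 1165 to 1792 higher and 841 to 1358 lower for eds1-2 against Col-0. Kept genes ran from 620 to 1123 and 372 to 722 for eds1-2 (shares 0.1031 to 0.2816 and 0.09327 to 0.2176) and from 1901 to 3072 lower for sid2-1. Shared genes ran from 337 to 1346 and 490 to 1630, and opposite ones from 60 to 193 and 8 to 34.

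The cause of these moves was not tested. Changes of sign touched only results below the threshold. *DND1* had −0.0041 in TPR1-GFP with upper-quartile scaling, and without scaling −0.0603 in eds1-2 against TPR1-GFP and 0.0839 in sid2-1 against eds1-2. *ICS1* in eds1-2 against Col-0 had 0.1617 with limma-voom and −0.5361 to 0.5224 leaving out libraries. *DFR* had −0.1434 with limma-voom and −0.137 in the authors' columns for TPR1-GFP (−0.9647 to 0.958), and 0.2953 and 0.2887 for sid2-1 against TPR1-GFP (−0.7654 to 1.0462). Against Col-0 sid2-1 had −0.319 to 0.6344 for *DFR*, −0.9689 to 0.1205 for *EDS1B*, and −0.0668 to 0.0621 for *MRD1*, which had 0.1624 without scaling. In sid2-1 against TPR1-GFP, the values without scaling were −0.0464 for *SUC2* (−0.0129 to 0.0603), −0.0506 for *SAG101* (−0.0741 to 0.1094) and −0.0132 for *GSTF12* (−0.2352 to 0.3232), and ranges were −0.0944 to 0.3816 for *CBP60G*, −0.1975 to 0.0116 for *EDS1A* and −0.3016 to 0.1018 for *PAD4*. Between the double lines *TPR1* had 0.0648 without scaling (−0.1668 to 0.155) and *DND1* −0.0869 to 0.096. In eds1-2 against Col-0 ranges were −1.9006 to 0.2065 for *FMO1*, −3.4014 to 1.4353 for *ALD1*, −0.1423 to 0.3094 for *SOC1*, −0.3383 to 0.792 for *HEL* and −0.0602 to 0.1834 for *DND2*.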

Other observations

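The gene families in this part, the genes named from them and the tests of them were chosen only after the results were seen. Their p-values describe these data and are no independent test, least of all for anthocyanin genes, some of which were among the largest changes above. Genes of anthocyanin synthesis, which colours stressed leaves red, rose in the eds1-2 line alone among the 4 genotypes. *DFR*, the reductase that commits flavonoids to anthocyanin, stood at 0.233 CPM (SD 0.151) in Col-0, 0.31 CPM (SD 0.36) in TPR1-GFP, 0.257 CPM (SD 0.127) in the sid2-1 line and 76.0 CPM (SD 12.6) in the eds1-2 line, and the glutathione transferase gene *GSTF12* at 0.23, 0.35, 0.371 and 45.4 CPM. All 15 measured genes of the pathway were higher in the eds1-2 line than in TPR1-GFP (median 5.56, camera adjusted p = 1.72e-29, and adjusted p = 0.00241 with an estimated correlation). Against Col-0 13 were higher, or 14 adjusted over the list alone (median 5.37, camera adjusted p = 3.03e-59, and adjusted p = 0.000248 with an estimated correlation), and all 15 were lower in the sid2-1 line than in the eds1-2 line (median −4.84, camera adjusted p = 1.14e-41, and adjusted p = 0.00215 with an estimated correlation). In TPR1-GFP against Col-0 2 were lower, with a median of −0.24 that becomes 0.01 without scaling, and none passed in the sid2-1 line against TPR1-GFP.

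Of 81 TIR-type receptor genes 70 were higher and 2 lower in TPR1-GFP than in Col-0 (median 1.15, camera adjusted p = 7.84e-18, and adjusted p = 0.406 with an estimated correlation). In the eds1-2 line 3 were higher and 60 lower than in TPR1-GFP, or 3 and 61 adjusted over the list alone (median −0.93, camera adjusted p = 1.70e-15, and adjusted p = 0.6 with an estimated correlation). Receptors with a coiled-coil domain were higher in TPR1-GFP than in Col-0 in 18 of 22 cases, or 20 adjusted over the list alone (median 0.49, camera adjusted p = 1.43e-05, and adjusted p = 0.406 with an estimated correlation). In the same comparison lectin kinases counted 27 higher and 8 lower of 47, or 28 and 9 adjusted over the list alone (median 0.61, camera adjusted p = 0.00998, and adjusted p = 0.406 with an estimated correlation). Histone genes were lower in TPR1-GFP than in Col-0 in 21 of 29 cases and higher in 3 (median −0.93, camera adjusted p = 1.50e-05, and adjusted p = 0.406 with an estimated correlation). In the eds1-2 line 19 of 29 were lower than in Col-0, or 22 lower and 1 higher adjusted over the list alone (median −0.68, camera adjusted p = 7.06e-09, and adjusted p = 0.274 with an estimated correlation). In the sid2-1 line 19 were lower and 3 higher than in Col-0, or 21 and 3 adjusted over the list alone (median −0.59, camera adjusted p = 3.89e-05, and adjusted p = 0.342 with an estimated correlation). Of 228 genes described as ribosomal proteins 87 were lower and 9 higher in TPR1-GFP than in Col-0, or 72 and 9 adjusted over the list alone (median −0.39, camera adjusted p = 2.41e-05, and adjusted p = 0.724 with an estimated correlation). Against Col-0 the sid2-1 line had 90 lower and 9 higher, or 91 and 9 adjusted over the list alone (camera adjusted p = 1.14e-06, and adjusted p = 0.679 with an estimated correlation). The eds1-2 line had 5 lower and 1 higher, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.0052, and adjusted p = 0.846 with an estimated correlation). Transposable element genes, glutathione transferases, UDP-glycosyltransferases and leucine-rich repeat kinases did not pass the camera test in TPR1-GFP against Col-0, at adjusted p = 0.651, 0.157, 0.515 and 0.866.

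Aliphatic glucosinolate genes were higher in the eds1-2 line than in Col-0 in 7 of 12 cases, or 8 adjusted over the list alone (median 0.85, camera adjusted p = 0.000176, and adjusted p = 0.403 with an estimated correlation), while *IMS2* of side-chain elongation was lower. Against TPR1-GFP the eds1-2 line had 2 higher and 2 lower of 12 (camera adjusted p = 0.528). TPR1-GFP itself had 4 higher and 1 lower than Col-0 (camera adjusted p = 0.101). The sid2-1 line had 1 higher and 9 lower than the eds1-2 line (camera adjusted p = 0.0113, and adjusted p = 0.919 with an estimated correlation). *MRD1* stood at 28.3 CPM (SD 1.11) in Col-0 and 28.1 CPM (SD 2.54) in the sid2-1 line but at 0.276 CPM (SD 0.167) in TPR1-GFP and 0.123 CPM (SD 0.0476) in the eds1-2 line, with no overlap between the pairs.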
